A study of Mus musculus with 8 samples.

How the data were processed

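Total RNA of R1 mouse embryonic stem cells was hybridised to Affymetrix gene arrays, 1 array per sample. The deposited log2 values are probe-set summaries that the authors made with RMA, per the submitters' processing notes; the RMA version, software and array library file are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises probes, and it pulls the arrays' distributions together, so a change shared by most genes would not appear. The deposited table held 28815 probe sets. Of these 21780 had exactly 1 gene symbol in the platform annotation, 1605 had several and 5430 had none in the annotation table used here. Probe sets with several symbols were not named. Each gene was represented by its probe set with the highest mean over the 8 arrays, which gave 19935 genes, 998 of them with more than 1 probe set to choose from. Symbols were compared with RefSeq through the gene identifier, found for 21689 probe sets, and 0 changed. No coordinates are given, because no genome build is named for the values. No 2 arrays held identical values.

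Groups and replicate numbers were taken from the sample titles, which use the word differentiation while the series title and growth protocol say pluripotent conditions; the text follows the latter. The design, the comparisons, the gene lists, the rule for named genes and all but 2 of the alternatives below were fixed before the data were examined. Limma (version 3.58.1 in R 4.3.3) fitted a mean per group to all 8 arrays, and moderated tests (lmFit, eBayes) gave 4 comparisons: the average of both siRNAs against control, each siRNA against control, and siRNA 2 against siRNA 1. P-values were two-sided and adjusted by Benjamini-Hochberg over the 19935 genes, with a gene called at an adjusted p under 0.05. Standard errors and 95% intervals are those of this model. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

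The 23 gene lists covered pluripotency and lineage genes, signalling targets, metabolism and stress responses, calcineurin, and markers of other cells. They were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance in a direction. Lists needed at least 3 tested members, and 372 genes belonged to at least 1 list. List symbols were matched to the annotation by symbol or synonym. Of the 10 genes listed for the 2-cell-like state 5 were tested, and Zscan4c, Zscan4d, Zscan4f, Tcstv1 and Usp17le were not.

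The rule for named genes took up to 12 called genes per direction (6 between the siRNAs) with the largest difference, all siRNA arrays on the same side of all controls and a mean above the median gene in the brighter group. Where no gene was called, which was so in all 4 comparisons, it took the 5 per direction with the smallest unadjusted p, leaving out predicted gene models. It added Ppp3cb, the calcineurin list and up to 4 members of each list with the smallest unadjusted p for the average of both siRNAs.

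The procedure was tested on simulated data before use: 200 of the 19935 genes were given known changes, with noise either independent between genes or correlated between genes as on the real arrays, over 20 draws. Each draw held changes of 0.25, 0.5, 1 and 2 on the log2 scale in equal numbers of genes. The larger changes make the adjusted threshold easier to pass for the smaller ones. The share recovered was computed for the comparisons with control, not between the siRNAs, and is given with them. Unchanged groups sharing the control arrays were simulated 100 times with each kind of noise. Simulated lists shifted by 0.25 on the log2 scale were called in 100% of cases with the preset correlation, which also called 3.55 unshifted lists on average, and in 76.7% with an estimated correlation, which called 0 unshifted lists. For a shift of 0.1, nearer the list differences seen here, these were 86.7% with 3.7 unshifted lists, and 23.3% with 0.

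The alternatives were quantile normalization repeated over the tested genes, centring of arrays on their medians, a filter at the median mean expression, eBayes with trend and robust moderation, array weights, all probe sets, the mean of a gene's probe sets, fits of only the groups compared, a replicate block, and leaving out each array in turn. After the data were seen 2 more were added: the lower quartile of each array as a covariate, and leaving out siRNA 1 replicates 1 and 2 together. Ranges given for a list are over all 19 fits with camera's preset correlation, and the estimated correlation and fry are given apart. The exact permutation tests of Ppp3cb enumerate all splits of the arrays compared. For arrays with the same replicate number, deviations from the group means did not go together, so the numbers were not taken to pair the samples.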

Results

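Gene expression was measured by microarray in R1 cells, a mouse embryonic stem cell line, kept under pluripotent conditions and collected 48 hours after transfection with small interfering RNA (siRNA). The series held 8 arrays in 3 groups. There were 3 arrays of cells given a control siRNA, 3 of cells given siRNA 1 against CnAb1 and 2 of cells given siRNA 2 against CnAb1. CnAb1 is a splice variant of the beta catalytic subunit of calcineurin, a calcium-dependent phosphatase, encoded by Ppp3cb. The question was which transcripts differ in stem cells when this variant is targeted, and whether both siRNAs give the same differences. Values are log2 expression per probe set, and the median of an array lay between 8.12 and 8.20. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of each value.

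The arrays were alike over all 19935 genes tested, with correlations between pairs of arrays from 0.9949 to 0.9989. The leading axis of variation (first principal component, 45.2% of the variance) did not follow the groups: siRNA 1 replicate 1 lay at its low end with a score of -13.2 and siRNA 1 replicate 2 at its high end with 15.7. The score followed the lower quartile of each array, which ran from 6.81 to 6.98 on the log2 scale. Across the 8 arrays Pearson's r was 0.967 (two-sided exact permutation p = 2.5e-05) and Spearman's rho was 1 (exact permutation p = 5e-05), each the smallest p the permutations can give. Without the 2 arrays farthest from the median lower quartile r was 0.917 (exact permutation p = 0.0014). This was the only relation across arrays that was computed, apart from its repeat without an array. Score and lower quartile come from the same values of each array and are not independent measures, so these p-values do not bear on a cause. The 1015 olfactory receptor genes, which encode the odorant receptors of olfactory neurons, deviated from their means by 0.08 on siRNA 1 replicate 2 and by -0.03 on siRNA 1 replicate 1 on average, while genes from the 60th to the 80th percentile of mean expression deviated by -0.07 and 0.07 on those arrays (all log2).

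**Figure D1:**
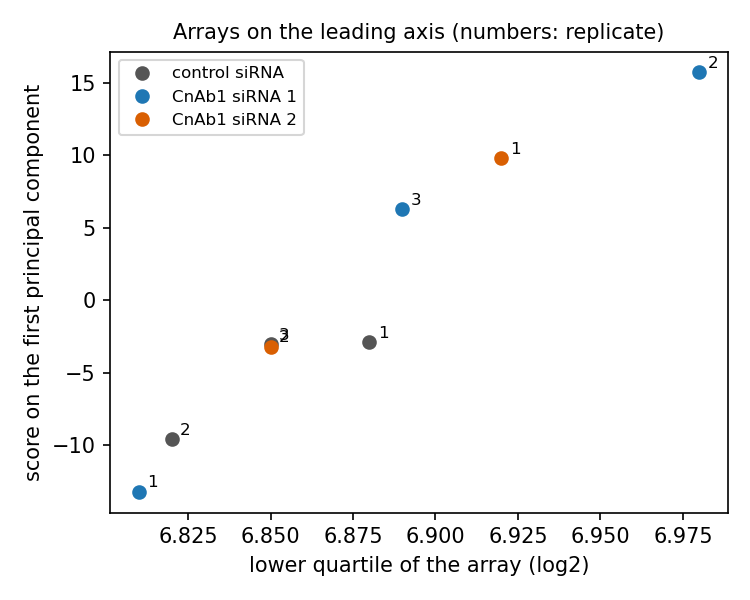
Score of each array on the first principal component (vertical axis, no unit) against the lower quartile of its log2 values (horizontal axis), 1 point per array, coloured by group and numbered by replicate. The 3 siRNA 1 arrays hold both ends of the axis, at -13.2 and 15.7.

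The targeted gene was looked at first. Ppp3cb was not lower on the siRNA arrays. Its probe set (10417895) read 10.63 ± 0.07 (SD, n = 3) with control siRNA, 10.76 ± 0.29 (n = 3) with siRNA 1 and 11.11 ± 0.07 (n = 2) with siRNA 2, all log2. The siRNA 1 arrays parted: replicates 1 and 2 read 10.52 and 10.68, inside or just below the control range of 10.55 to 10.70, and replicate 3 read 11.09, next to the siRNA 2 arrays at 11.07 and 11.16. The average of both siRNAs lay 0.31 above control (SE 0.11, 95% interval 0.06 to 0.56, 1.24-fold), siRNA 1 lay 0.13 above (SE 0.12) and siRNA 2 lay 0.49 above (SE 0.14). None passed the threshold: limma's adjusted p was 0.769, 0.88 and 0.794. Two-sided exact permutation p was 0.7 for siRNA 1 and 0.1 for siRNA 2, where the 10 splits of 5 arrays allow no p under 0.1. For the mean of all 5 siRNA arrays, which weights arrays and not siRNAs equally and lay 0.274 above control, exact permutation p was 0.196. The siRNA 1 difference was -0.029 without replicate 3. With array weights it was 0.388 and passed (adjusted p = 0.0355, against 0.0355 to 1 over all alternatives). The probe set is assigned to the gene and not to a splice variant, and which of its probes lie in CnAb1 sequence is not known here, so these values do not check the knockdown.

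The calcineurin list, 16 genes for calcineurin subunits, its regulators and NFAT transcription factors, of which calcineurin activates all but Nfat5, gave differences in both directions. Between control and the siRNA average, 8 of the 16, Ppp3cb among them, were higher and 8 lower, the median difference was 0.002 and 0 were called, also when adjusted over the list alone. Ppp3ca, the alpha catalytic subunit, read 9.99 ± 0.05 (SD, n = 3) in control cells and differed by -0.09 (SE 0.06). Rcan1, a calcineurin inhibitor whose transcription NFAT drives, read 10.21 ± 0.08 (n = 3) in control cells and differed by -0.06 (SE 0.06). Rcan3, of the same family, differed by 0.11 (SE 0.05) and lay above every control on 5 of 5 siRNA arrays. Ppp3cc differed by -0.02 (SE 0.05), a sign that turned without siRNA 2 replicate 1 (0.022), without siRNA 1 replicates 1 and 2 together (0.004) and with the array lower quartile as a covariate (0.013). Nfat5 differed by -0.15 (SE 0.12), Chp1 by -0.07 (SE 0.07), Ppp3r1 by -0.07 (SE 0.06) and Nfatc3 by 0.07 (SE 0.07), which turned to -0.013 without siRNA 1 replicates 1 and 2 together. The list as a whole had an adjusted p of 0.876 in limma's camera test, and adjusted p = 0.984 with an estimated correlation.

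**Figure D2:**
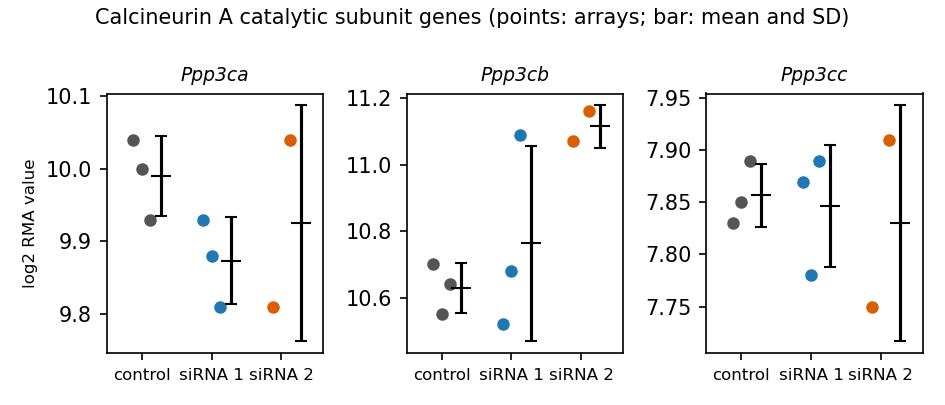
Log2 RMA values (vertical axis) of the 3 calcineurin A catalytic subunit genes in the control, siRNA 1 and siRNA 2 groups, 1 point per array, with the mean and SD of each group beside the points. Ppp3cb reads 10.52 to 11.16 on the siRNA arrays and 10.55 to 10.70 on the control arrays.

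The main comparison set the average of both siRNAs against control. The genes nearest to a call were lower for Gtsf1, a germ-cell factor of the piRNA pathway, by -0.38 (SE 0.06), for Actn3, a muscle alpha-actinin, by -0.31 (SE 0.05), for Tdpoz3, a gene of early embryos, by -0.71 (SE 0.11), for Eif4a3l1 by -0.45 (SE 0.08), and for the exporter gene Slc47a1 by -0.32 (SE 0.05). They were higher for Crip1 by 0.25 (SE 0.04), for Sox15, a Sox transcription factor of stem cells, by 0.40 (SE 0.07), for Krt25 by 0.27 (SE 0.05), for Doxl2 by 0.26 (SE 0.05) and for Nanos3, a germ-cell RNA-binding protein, by 0.27 (SE 0.05). Krt25 and Doxl2 were dim, with control means of 6.58 and 6.66, below the lower quartile of every array (6.81 to 6.98). Whether they were detected is unknown. Each of these 10 genes lay outside the control range in the same direction on 5 of 5 siRNA arrays. They were picked by p from these same arrays, which favours such a separation, so it is no separate support. Sox15 read 10.59 ± 0.08 (SD, n = 3) in control cells, 10.91 ± 0.13 (n = 3) with siRNA 1 and 11.07 ± 0.12 (n = 2) with siRNA 2, and Gtsf1 read 8.11 ± 0.07, 7.87 ± 0.01 and 7.58 ± 0.11 in the same groups. None of them passed the threshold, as limma's adjusted p was 0.508 for each, and the difference of a gene picked for its small p overstates what new arrays would show.

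In this comparison limma called 0 of 19935 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1257 genes (653 higher, 604 lower), where 997 would be chance, and the smallest adjusted p was 0.508. That unadjusted count was 443 without control replicate 2, 831 without siRNA 2 replicate 1 and 3589 without siRNA 1 replicate 1. Another weighting of the arrays (limma's array weights) called 14 genes, among them 6 of the 10 above, Gtsf1, Actn3, Crip1, Sox15, Krt25 and Doxl2 (adjusted p = 0.0401 each, in a range of 0.0401 to 1 over all alternatives), and 0 were called by every other fit tried. No gene differed 2-fold, and the largest difference was 0.71 on the log2 scale. The 95% interval lay within 2-fold for 19934 genes (99.99%) and within 1.5-fold for 99.8%. Simulated changes of 0.5 on the log2 scale, with gene-to-gene correlation as on these arrays, were recovered for 78.7% of changed genes in this comparison, those of 0.25 for 27.5% and those of 1 for 98.5%. The same draws held changes of 1 and 2, which no gene reached here, so the shares for smaller changes may be too high. All siRNA arrays lay on the same side of all controls for 4.7% of genes, where chance gives 3.6%.

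**Figure D3:**
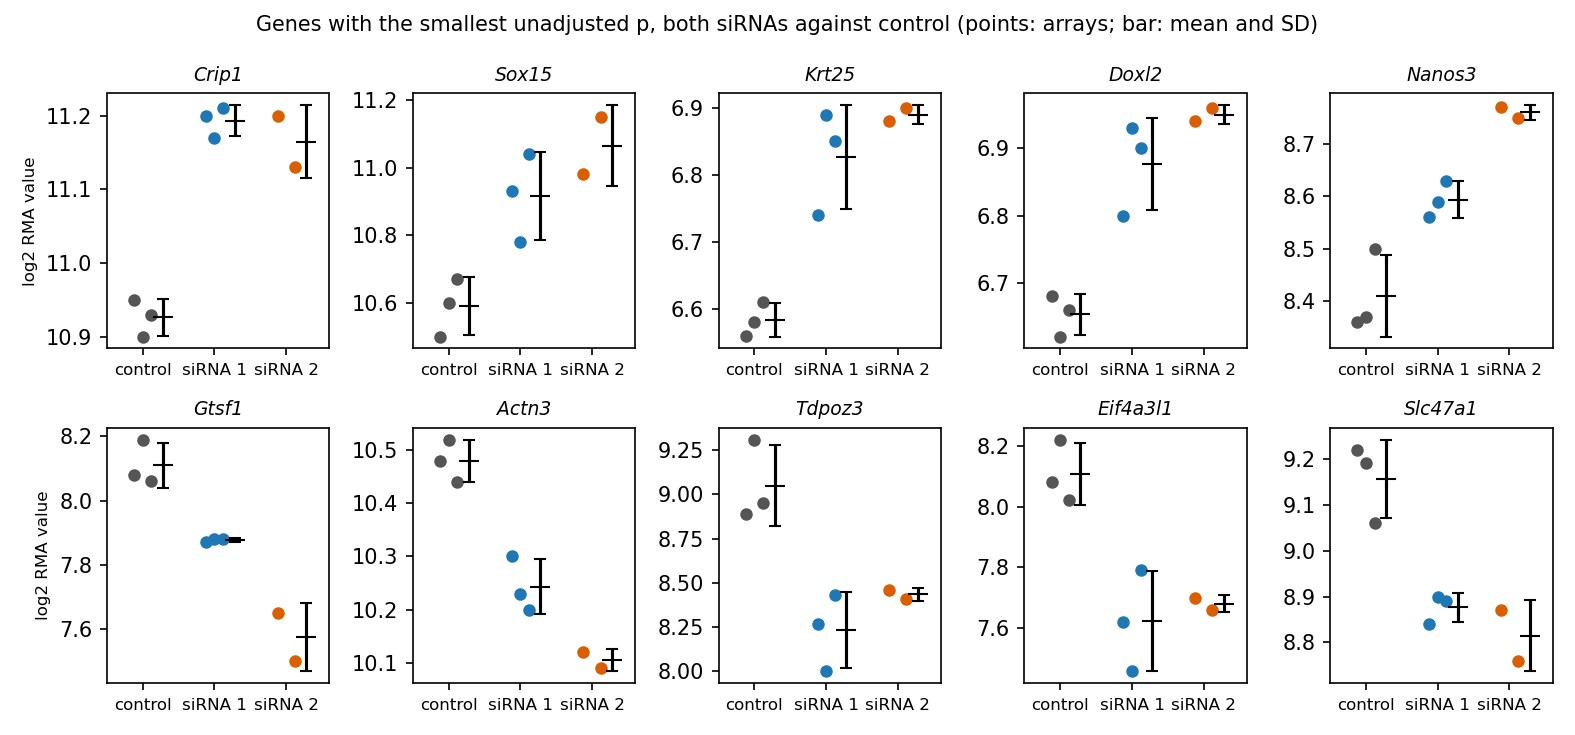
Log2 RMA values (vertical axes, each with its own range) of the 10 genes with the smallest unadjusted p between both siRNAs and control, 1 point per array, with the mean and SD of each group beside the points. For each gene all 5 siRNA arrays lie outside the control range, which picking by small p favours. None of the genes passes the threshold (limma adjusted p = 0.508).

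Pluripotency factors showed no shift between control and the siRNA average. Of the 25 general and naive pluripotency factors 14 were higher and 11 lower, with a median of 0.003, 0 called and 0 called when adjusted over the list alone. Dppa3, a maternal factor of naive cells, differed most, by 0.32 (SE 0.08, adjusted p = 0.769 in limma) and lay above the controls on 5 of 5 siRNA arrays, Utf1 by 0.10 (SE 0.06), Zfp42 by -0.12 (SE 0.07) and Klf2 by -0.09 (SE 0.07). The 14 formative and primed epiblast genes had a median of -0.035, with Nodal at -0.12 (SE 0.05), Fgf15 at -0.11 (SE 0.05), Cdh2 at -0.12 (SE 0.07) and Cldn6 at 0.18 (SE 0.07). Neither list was called (camera adjusted p 0.887 and 0.236).

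Genes of the embryonic lineages lay near their control levels. Median differences were 0.017 over 22 primitive streak and mesoderm genes, 0.034 over 18 primitive and definitive endoderm genes, -0.01 over 18 neuroectoderm genes and 0.026 over 14 trophectoderm genes, and 0 members were called in any of them. Cer1, a secreted Nodal and BMP inhibitor, differed by -0.32 (SE 0.09) and Bmp4 by 0.19 (SE 0.06). Map2 differed by -0.19 (SE 0.05) and Meis2 by -0.19 (SE 0.06), both below the controls on 5 of 5 siRNA arrays. Sparc differed by 0.12 (SE 0.05) and Tead4 by 0.14 (SE 0.06). Camera gave these 4 lists adjusted p-values of 0.575, 0.306, 0.236 and 0.236.

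Signalling targets were measured for pathways that calcineurin, Akt and Wnt are known to reach. The medians were 0.011 over 17 Wnt/beta-catenin target genes, -0.026 over 13 Nodal/Activin target genes, 0.038 over 12 BMP target genes, -0.029 over 18 FoxO target genes and 0 over 20 genes of the mTOR complexes, Akt and the COG complex. Rnf43, a Wnt target, differed by 0.11 (SE 0.06), Lefty2, a Nodal target, by -0.10 (SE 0.05), Smad6, a BMP target, by 0.15 (SE 0.05), Sesn3, a FoxO target, by -0.16 (SE 0.06) and Akt1 by 0.13 (SE 0.06). Camera's adjusted p was 0.764, 0.236, 0.236, 0.199 and 0.567 in that order, and 0 members were called. The FoxO target genes were called by 1 of the 19 alternatives, the fit without siRNA 2 replicate 2, with a mean of -0.057 in place of -0.033 (adjusted p = 0.0352, range 0.0352 to 0.806, and adjusted p = 0.778 with an estimated correlation).

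Metabolic and stress responses were also near their control levels. The medians were -0.001 over 14 serine and one-carbon genes, 0.003 over 20 ATF4 and amino acid response genes, 0.03 over 20 interferon response genes, -0.009 over 17 p53 target genes, -0.014 over 23 cell cycle genes, -0.042 over 15 unfolded protein response genes and 0.007 over 19 glycolysis and hypoxia genes, with camera adjusted p from 0.174 to 0.99. Psph, an enzyme of serine synthesis, differed by -0.14 (SE 0.05), Cebpb by 0.16 (SE 0.06), Oasl1 by 0.18 (SE 0.05), Eda2r by -0.15 (SE 0.04), Ccnd2 by -0.12 (SE 0.06), Xbp1 by -0.07 (SE 0.05) and Tpi1 by 0.08 (SE 0.05). None of them was called.

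Camera called 2 of the 23 lists, both lower. The 5 tested members of the list of 2-cell-like state genes, transcripts of the rare stem cells that resemble early embryos, had a median of -0.198 and all 5 were lower (adjusted p = 0.000504, and adjusted p = 0.778 with an estimated correlation). None of the listed Zscan4 genes was among the tested members. Usp17la differed by -0.49 (SE 0.18), Tmem92 by -0.28 (SE 0.10), Usp17lc by -0.20 (SE 0.11) and Tcstv3 by -0.16 (SE 0.05), and 0 were called over all genes while 3 passed when adjusted over the list alone. Usp17la and Usp17lc are close paralogs, and whether their probes tell them apart was not examined. Control replicate 2 held the highest Usp17la value, 8.43, against 7.43 and 7.87 on the other controls, and without that array the mean difference of the list was -0.135 in place of -0.25 (camera adjusted p = 0.0228). Of the 18 cholesterol synthesis genes 14 were lower, with a median of -0.039 (adjusted p = 0.0405, and adjusted p = 0.778 with an estimated correlation), among them Nsdhl at -0.12 (SE 0.05) and Msmo1 at -0.12 (SE 0.05). The cholesterol call was lost without control replicate 1 (adjusted p = 0.179), siRNA 1 replicate 1 (0.0948), siRNA 1 replicate 2 (0.227) or siRNA 2 replicate 1 (0.26), in a range of 0.00231 to 0.635 over all alternatives. The mean of that list was -0.044 with all arrays, and -0.02, -0.049, -0.026 and -0.024 without these arrays in that order. With an estimated correlation or with fry, 0 lists were called, and on simulated unchanged groups with gene-to-gene correlation as on these arrays the preset correlation called a median of 3 lists.

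Markers of other cell types were measured beside these groups. The 18 fibroblast (feeder cell) markers had a median of 0.098 (camera adjusted p = 0.149, and adjusted p = 0.778 with an estimated correlation), with Col1a2 at 0.17 (SE 0.06), Col1a1 at 0.14 (SE 0.05), Acta2 at 0.22 (SE 0.09) and Twist1 at -0.14 (SE 0.05). The mean of the fibroblast markers was 0.064, and camera called them under 5 alternatives, with means of 0.094, 0.081 and 0.083 without control replicate 3 (0.0101), siRNA 1 replicate 2 (0.0303) and siRNA 1 replicate 3 (0.0241), 0.095 with the expression filter (0.000307) and 0.096 with the lower quartile as a covariate (0.00519). Over all alternatives their adjusted p ranged from 0.000307 to 0.794. The mean was smaller without control replicate 2 or without siRNA 1 replicate 1, the arrays where the list lay lowest and highest. The 9 macrophage and blood cell markers had a median of 0.011 (camera adjusted p = 0.764), with Csf1r at 0.09 (SE 0.05) and Cd68 at -0.10 (SE 0.08). Both lists were highest on siRNA 1 replicate 1, where their means lay 0.19 and 0.20 above their means over all arrays.

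**Figure D4:**
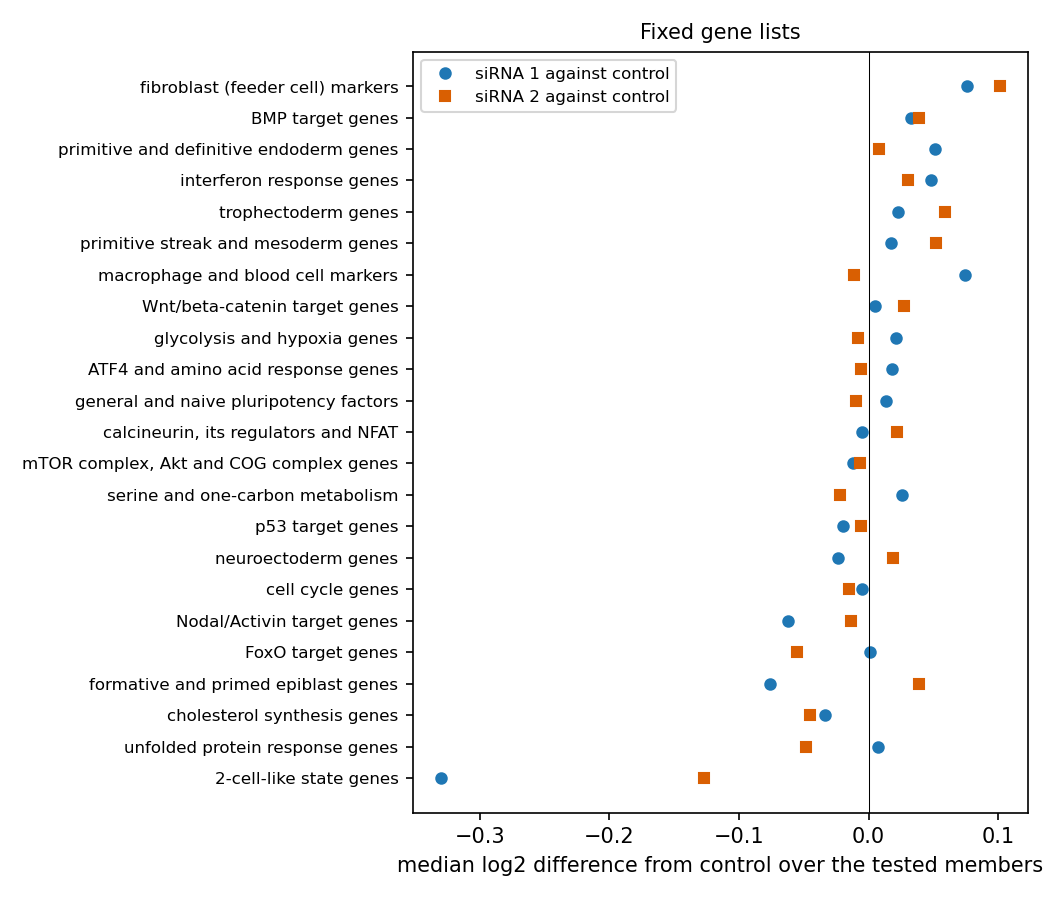
Median log2 difference from control over the tested members of each of the 23 gene lists (horizontal axis), with circles for siRNA 1 and squares for siRNA 2, ordered by the median for the average of both. The list of 2-cell-like state genes lies lowest for both, at -0.33 for siRNA 1 and -0.127 for siRNA 2.

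With siRNA 1 alone, the genes nearest to a call were Amot, an angiomotin of cell junctions, at -0.43 (SE 0.06), Tdpoz3 at -0.81 (SE 0.13), H60b at -0.54 (SE 0.09), Eif4a3l1 at -0.48 (SE 0.09) and Arg2, an arginase, at -0.33 (SE 0.06). On the higher side were Crip1 at 0.26 (SE 0.05), the chemokine gene Ccl2 at 0.35 (SE 0.07), the cytokine subunit gene Il23a at 0.32 (SE 0.07), Leng9 at 0.24 (SE 0.05) and Ceacam15 at 0.22 (SE 0.05). Ceacam15 was dim, with means of 6.52 in control cells and 6.74 with siRNA 1, below the lower quartile of every array. Cer1 differed by -0.55 (SE 0.10). Limma's adjusted p was 0.805 for these genes, so none passed. Amot read 9.07 ± 0.02 (SD, n = 3) in control cells and 8.64 ± 0.10 (n = 3) with siRNA 1.

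Limma called 0 genes for siRNA 1, with 1063 at an unadjusted p under 0.05 (604 higher, 459 lower). That count was 427 without control replicate 2 and 4006 without siRNA 1 replicate 1, and array weights called 1436 genes (630 higher, 806 lower), among them Amot at -0.42, Crip1 at 0.28, Ccl2 at 0.23, Il23a at 0.32, H60b at -0.48 and Arg2 at -0.26. These weights were 3.56 for siRNA 1 replicate 3 and 0.31 and 0.41 for replicates 1 and 2, so that fit rests mostly on 1 siRNA 1 array. The other fits tried called 0.

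Camera called 5 lists for siRNA 1, and adjusted p was 0.554 or higher with an estimated correlation for each of them. The 2-cell-like state genes had a median of -0.33 with 5 of 5 lower (adjusted p = 1.28e-06), and 4 passed when adjusted over the list alone. That call was lost without siRNA 1 replicates 1 and 2 together (adjusted p = 0.0992, mean -0.253), in a range of 2.61e-10 to 0.0992 over all alternatives. The formative and primed epiblast genes had a median of -0.076 with 12 of 14 lower (adjusted p = 0.000528), with Cdh2 at -0.27 (SE 0.08). This call was lost without siRNA 1 replicate 1 (adjusted p = 0.0695, range 1.53e-06 to 0.448 over all alternatives), where the mean of the list was -0.074 in place of -0.077. Without siRNA 1 replicate 2 the mean was -0.049 and the list was still called (0.0179), and the call was also lost with array weights (0.28, mean -0.026) and without siRNA 1 replicates 1 and 2 together (0.448, mean -0.016). The Nodal/Activin target genes had a median of -0.062 and the cholesterol synthesis genes of -0.034, and the fibroblast (feeder cell) markers of 0.076 (adjusted p = 0.0393 each). The mean of the fibroblast markers was 0.084, and 0.012 without siRNA 1 replicate 1 (adjusted p = 0.942), 0.049 without control replicate 2 (0.216) and 0.089 without control replicate 1 (0.0814), in a range of 0.00047 to 0.942 over all alternatives. The Nodal/Activin call was lost without any of 4 arrays, namely control replicate 2 (0.0611), control replicate 3 (0.11), siRNA 1 replicate 1 (0.088) and siRNA 1 replicate 2 (0.236), in a range of 0.0156 to 0.448. The mean of that list was -0.042 with all arrays, and -0.046, -0.044, -0.059 and -0.018 without these arrays in that order. The cholesterol call was lost without control replicate 1 (0.206), siRNA 1 replicate 1 (0.088) and siRNA 1 replicate 2 (0.642). The mean of that list was -0.034 with all arrays, and -0.011, -0.045 and 0.002 without these arrays in that order. Without siRNA 1 replicate 3 the mean was -0.06. Its adjusted p ranged from 0.00048 to 0.901. With fry, 1 list was called, the neuroectoderm genes (adjusted p = 0.0483, median -0.024), which camera did not call with the preset correlation (0.0796) and which had adjusted p = 0.554 with an estimated correlation. Camera called that list without control replicate 1 (0.0403) or siRNA 1 replicate 3 (0.0383), in a range of 0.0383 to 0.448. The p53 target genes were called without siRNA 1 replicate 3 (0.0383, mean -0.031 in place of -0.018, range 0.0383 to 0.822) and the endoderm genes with the expression filter (0.018, mean 0.059 in place of 0.062, range 0.018 to 0.699). Both had adjusted p = 0.554 with an estimated correlation.

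With siRNA 2 alone, the genes nearest to a call were Gtsf1 at -0.53 (SE 0.07), Actn3 at -0.38 (SE 0.06), the serpin gene Serpinb6c at -0.71 (SE 0.12), Rsph9 at -0.36 (SE 0.06) and Zfy1 at -0.41 (SE 0.08). On the higher side were Nanos3 at 0.35 (SE 0.06), Sox15 at 0.48 (SE 0.09), Krt25 at 0.30 (SE 0.06), Doxl2 at 0.30 (SE 0.06) and Hip1 at 0.37 (SE 0.08). Serpinb6c read 9.07 ± 0.06 (SD, n = 3) in control cells and 8.36 ± 0.17 (n = 2) with siRNA 2. Limma's adjusted p was 0.369 for Gtsf1 and 0.651 for the others, so none passed.

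Limma called 0 genes for siRNA 2, with 1211 at an unadjusted p under 0.05 (510 higher, 701 lower), and 0 were called by the other fits tried, array weights included. The unadjusted count was 579 without control replicate 2 and 1979 without siRNA 1 replicate 1. With all arrays camera called 0 of the 23 lists with the preset correlation, 0 with an estimated correlation, and fry called 0. With the preset correlation 7 lists were each called by 1 alternative, and each had adjusted p = 0.932 with an estimated correlation. Without control replicate 1 these were the 2-cell-like state genes (mean -0.261 in place of -0.155, adjusted p = 0.00173, range 0.00173 to 0.684), the trophectoderm genes (0.099 in place of 0.072, 0.0441, range 0.0441 to 0.366) and the unfolded protein response genes (-0.046 in place of -0.052, 0.0441, range 0.0441 to 0.31). Without siRNA 2 replicate 2 they were the cholesterol synthesis genes (-0.094 in place of -0.053, range 0.00842 to 0.751) and the FoxO target genes (-0.098 in place of -0.05, range 0.00842 to 0.891), at 0.00842 each. With the expression filter they were the fibroblast markers (0.082 in place of 0.045, 0.0175, range 0.0175 to 0.684) and the mesoderm genes (0.063 in place of 0.053, 0.0397, range 0.0397 to 0.458). In simulation 63% of changes of 0.5 on the log2 scale were recovered for this comparison, and 72.2% for siRNA 1. The draws also held changes of 1 and 2, so both shares may be too high for differences as small as those seen here.

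No gene was called for both siRNAs, and likeness of their differences beyond the shared controls was not shown. Across genes, which are not independent replicates, the log2 differences had r = 0.586, and 69.6% of genes had the same sign. Both comparisons share the 3 control arrays. Simulated unchanged groups, also with shared controls but with every array drawn anew, gave r with 95% limits of 0.437 and 0.462 with independent noise. With correlated noise the limits were -0.786 and 0.907. The covariance was 0.00506, against a simulated mean of 0.00291 with independent and 0.00257 with correlated noise, whose 95% limits were -0.00354 and 0.0132. Genes at an unadjusted p under 0.05 in both comparisons and in the same direction numbered 260, where independent lists would share 31.6 and simulated unchanged groups shared 196.1 on average with independent noise. With correlated noise they shared a median of 1 and a mean of 177.9, with 95% limits of 0 and 1889. The values of r, covariance and shared genes thus lay inside the 95% limits that unchanged groups gave with correlated noise. The r was 0.282 without siRNA 2 replicate 1 and 0.369 without siRNA 1 replicate 2.

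**Figure D5:**
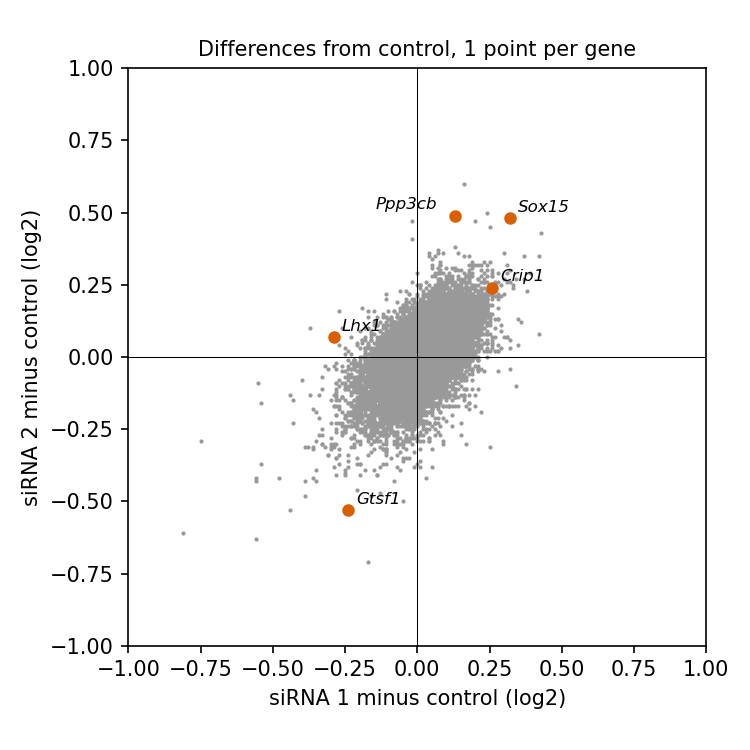
Log2 difference from control with siRNA 1 (horizontal axis) and with siRNA 2 (vertical axis), 1 point per gene for 19935 genes, with Ppp3cb, Gtsf1, Sox15, Crip1 and Lhx1 marked. Points lie along the diagonal (r = 0.586 across genes), and no gene was called in either comparison.

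Set directly against each other, siRNA 2 and siRNA 1 gave the smallest unadjusted p for genes that included Fabp3, a fatty acid binding protein, at -0.47 (SE 0.06), Crabp1, a retinoic acid binding protein, at -0.33 (SE 0.06), the metallothionein gene Mt1 at -0.32 (SE 0.06), Renbp at -0.39 (SE 0.07) and Fam183b at -0.37 (SE 0.07). On the higher side with siRNA 2 were Lhx1, a transcription factor of the primitive streak, at 0.36 (SE 0.06), Dgkk at 0.47 (SE 0.09), Itga1 at 0.43 (SE 0.09), Trim67 at 0.24 (SE 0.05) and Plxdc2 at 0.31 (SE 0.07). Fabp3 read 11.79 ± 0.04 (SD, n = 3) in control cells, 11.96 ± 0.06 (n = 3) with siRNA 1 and 11.49 ± 0.07 (n = 2) with siRNA 2. Limma's adjusted p was 0.482 for Fabp3, and none of them passed. With a variance trend and robust moderation 3 genes were called, Fabp3 (adjusted p = 0.0151), Crabp1 and Mt1 (0.0476 each), each the smallest over all alternatives, where the largest was 1.

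Limma called 0 genes between the siRNAs, with 893 at an unadjusted p under 0.05 (290 higher, 603 lower with siRNA 2), and the other fits called 0 apart from the 3 above. The unadjusted count was 1496 without siRNA 1 replicate 1, 1579 without siRNA 1 replicate 2 and 421 without siRNA 2 replicate 2. Camera called 3 lists, all higher with siRNA 2, and with an estimated correlation each had adjusted p = 0.653. The formative and primed epiblast genes had a median difference of 0.094 (adjusted p = 4.35e-05, 12 of 14 higher), with Cdh2 at 0.31 (SE 0.09). The 2-cell-like state genes had a median of 0.185 (adjusted p = 0.0107, 5 of 5 higher) and the primitive streak and mesoderm genes of 0.039 (adjusted p = 0.0294, 14 of 22 higher), with Cer1 at 0.46 (SE 0.11). Without siRNA 2 replicate 2 all 3 calls were lost (adjusted p 0.069, 0.0931 and 0.069), with list means of 0.055, 0.126 and 0.055 in place of 0.106, 0.19 and 0.061. The 2-cell-like call was also lost without siRNA 1 replicate 2 (0.108, mean 0.145), and the mesoderm call without siRNA 1 replicate 1 (0.688, mean 0.015) and siRNA 2 replicate 1 (0.0685, mean 0.067). Over all alternatives these adjusted p-values ranged from 1.07e-06 to 0.182 for the formative and primed epiblast genes, from 0.000233 to 0.349 for the 2-cell-like genes and from 0.00231 to 0.694 for the mesoderm genes. Under some alternatives 7 other lists were called, with adjusted p from 0.653 to 0.822 with an estimated correlation. The calcineurin list was called under 5 (smallest adjusted p 0.012, without siRNA 2 replicate 1; range 0.012 to 0.744) and the serine and one-carbon genes under 3 (0.00817, without siRNA 1 replicate 2; range 0.00817 to 0.352). The trophectoderm genes, the pluripotency factors and the mTOR, Akt and COG genes were called under 2 each (ranges 0.00575 to 0.894, 0.00838 to 0.958 and 0.012 to 0.711), with the smallest values without siRNA 1 replicate 3, siRNA 2 replicate 2 and siRNA 2 replicate 1. The FoxO target genes were called without siRNA 2 replicate 2 (range 0.0205 to 0.775) and the unfolded protein response genes without siRNA 1 replicate 2 (range 0.0168 to 0.688).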

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

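The tests of the leading axis by loading and by group, those of the 2-cell-like list by correlation and by control replicate 2, and the test of a wrong sample label were chosen after the values they concern had been seen. The group test first used the permutation p given below and was then set on the range within siRNA 1. The other tests were written down first.

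The gene lists that differed between siRNA 2 and siRNA 1 by camera's test of the difference were the formative and primed epiblast genes (median 0.094), the primitive streak and mesoderm genes (0.039) and the 2-cell-like state genes (0.185). With an estimated correlation each had adjusted p = 0.653.

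The first pattern weighed was the low level of 2-cell-like state genes on the siRNA arrays, a mean shift of -0.25 for the average of both siRNAs. As deviations from the mean over all arrays, the list lay at -0.27 to -0.09 on the siRNA 1 arrays. On the siRNA 2 arrays it lay at -0.05 and 0.08, and on the controls at -0.04 to 0.4. With siRNA 2 alone camera did not call the list (adjusted p = 0.135). With an estimated correlation between genes the adjusted p was 0.778, so members that move together may account for the small p of the preset test. Without control replicate 2 the mean shift was -0.135 (SE over genes 0.032) against -0.25 (SE 0.065) with all arrays, and the spread leaves open whether that array makes most of it. With the lower quartile of the arrays as a covariate the shift was -0.192 (SE over genes 0.058). These SEs are over 5 genes that move together (estimated correlation 0.55) and do not measure the spread between arrays. They thus decide neither on control replicate 2 nor on a compressed intensity range, which stays open as a cause. An effect of the siRNAs stays open.

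The second pattern was the higher Ppp3cb on the siRNA arrays, by 0.31 on average, for which a response of the gene to the siRNAs stays open. With the lower quartile as a covariate the difference was 0.282 (SE 0.111), which argues, narrowly, against a compressed range as the whole cause. Replicate 3 of siRNA 1, whose Ppp3cb value is like that of siRNA 2, might carry a wrong label. On 100 genes that part the other siRNA arrays it lay at 0.61 (SE 0.05) on a scale from siRNA 1 (0) to siRNA 2 (1), but the siRNA 2 arrays themselves, placed the same way, lay at 0.28 and 0.50 and siRNA 1 replicate 2 at 0.70, so the test does not separate the groups and a wrong label cannot be told apart from a true value. The condition that siRNA 2 arrays reach 0.75 was added after this was seen, and without it the test would have argued against a wrong label.

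The third pattern was the leading axis between arrays. The siRNA 1 arrays alone span 100% of its range, and the groups explain 18.9% of it (exact permutation p = 0.607 over 560 assignments), which argues against the siRNA group as its cause. With siRNA 1 replicate 1 left out, the recomputed axis still followed the lower quartile (r = 0.964, exact permutation p = 2e-04, the smallest 5040 permutations can give). It held 44.5% of the variance, so an axis of this kind was present without that array. Score and lower quartile come from the same values, so this r and p do not decide on RNA of other cells on that array. Loadings and mean expression had a Spearman rho of -0.48 across genes, dim genes up where bright genes were down, as a compressed intensity range on some arrays would give. The loadings and the lower quartile come from the same values, so they are not separate support for it. No biological explanation other than the group was tested.

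The real groups were compared with splits of the arrays into groups of the same sizes, the real one counted among them. Of 100 splits of the 8 arrays 29 gave at least the 1257 genes at an unadjusted p under 0.05 that the average of both siRNAs gave, with 5669 as the highest of the others, so chance cannot be excluded, and counts several times the real one point to a structure of the samples. At least 2 called lists came from 84 of the 100 splits, with 9 as the highest, and chance cannot be excluded. The 10 splits of the control and siRNA 1 arrays are too few for a share under 0.05. The real one and others, 3 in all, gave at least the real 1063 genes at an unadjusted p under 0.05, with 3473 as the highest other. With array weights, 1 of 10 splits, the real one, gave as many as 1436 called genes, and the highest other gave 1077. The weights of that other split, and of 1 that gave 377, stopped short of convergence, while those of the real split converged, and the highest converged other gave 935.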

How the results depend on the processing

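The lower quartile covariate and the joint omission of siRNA 1 replicates 1 and 2 were chosen after seeing the data; the other 17 alternatives were planned. The counts of 0 called genes, for the average of both siRNAs, for each siRNA and between them, held under all of them except 2. Array weights called 14 genes for the average and 1436 for siRNA 1, and trend with robust moderation called 3 between the siRNAs; the cause was not tested. The count of genes called for both siRNAs was 0 throughout. The replicate block called 0 genes in each comparison and, for the average, 1 list. Deviations of same-numbered arrays had correlations across genes from -0.55 to 0.22, so no pairing by number was seen, though a weak one is not excluded. For the average, 2 lists were called; quantile normalization, array weights and the replicate block gave 1, the 2-cell-like genes. The expression filter gave 1, the fibroblast markers; the mean of the cholesterol synthesis genes stayed at -0.044 there (adjusted p = 0.317). The lower quartile covariate gave 2, the 2-cell-like genes and the fibroblast markers, and lost the cholesterol synthesis genes (mean -0.024, adjusted p = 0.364, range 0.00231 to 0.635), and an estimated correlation, fry and the joint omission gave 0. With the joint omission, on fewer samples, the means were -0.204 for the 2-cell-like genes (0.115, range 1.07e-07 to 0.115) and -0.018 for the cholesterol synthesis genes (0.635). The expression filter left fewer than 3 of the 2-cell-like genes and gave no value for that list. Leaving out each array gave 1 to 3 lists, with the 2-cell-like genes in each, and a correlation of the siRNA differences from 0.282 to 0.667. Without a siRNA 2 array that group has 1 array, assumed to vary like the others. The Ppp3cb difference for the average stayed positive, from 0.228 to 0.472 over all alternatives, with adjusted p from 0.075 to 1. The mean of the cholesterol synthesis genes for siRNA 1 turned sign to 0.013 with array weights, 0.017 with the joint omission and 0.002 without siRNA 1 replicate 2, the highest of the values without an array, whose lowest was -0.06; the cause was not tested. Of 144 results for named genes, with 2697 values under alternatives, 20 passed the threshold, 3 of them outside array weights, and 23 values of 7 uncalled results changed sign. Signal over background was not given, so which dim genes were detected is unknown.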

Other observations

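Some transcripts of macrophages and fibroblasts, not all, read higher on siRNA 1 replicate 1 than on any other array. Lyz2, a lysozyme of macrophages, read 11.12 there and 10.14 to 10.73 on the other 7 arrays, C1qb, a complement subunit, read 9.49 against 8.30 to 9.04, and Mpeg1 read 7.99 against 7.01 to 7.80. Of the matrix genes of fibroblasts, Postn read 9.27 against 8.47 to 8.77 and Fbln2 read 10.41 against 9.60 to 9.99. The collagens, the most abundant transcripts of fibroblasts, stood out little or not. Col1a1 read 9.52 against 9.28 to 9.52 and Col3a1 read 8.51 against 8.42 to 8.78, while Col1a2 read 9.19 against 8.82 to 9.15. Of the macrophage and blood cell genes, Csf1r read 7.57 against 7.42 to 7.64 and Ptprc read 7.33 against 6.98 to 7.36. Above every other array were Tyrobp at 8.43 against 7.78 to 8.18, Fcer1g at 8.22 against 7.67 to 8.04 and Cd68 at 10.20 against 9.87 to 10.15. On siRNA 1 replicate 1, 8 of 9 members of the macrophage and blood cell list lay above their means over the other arrays. The same held for 15 of 18 members of the fibroblast list. Mpeg1 and C1qb, on no list, were picked after their values were seen, and the others were picked from the 2 lists in the same way.

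Against 10000 random lists matched on mean expression, the median deviation of the macrophage and blood cell list on siRNA 1 replicate 1 lay at percentile 100. This comparison was meant as a test for RNA of other cells and was set aside, because the same list lay at percentile 99.9 on control replicates 1 and 2 and at 0 on control replicate 3, so an extreme percentile does not single out an array. The fibroblast list lay at percentile 100 on siRNA 1 replicate 1 and at 0 on control replicates 1 and 2.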
